A study of Mus musculus with 2 samples.

How the data were processed

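The data were single-cell RNA counts of tdTomato-positive retinal cells of mice aged 14 weeks, collected 8 weeks after AAV injection, in 2 libraries with 1 library per group. Per the submitters' protocol, the reporter-positive rate was about 4.9% in the test group and 10% in the control group, 60000 and 120000 positive cells were collected by the sort, and 27000 were loaded per library. The sample labelled Muller was taken as the test group because the other sample is labelled MullerControl. The deposited matrices hold counts, that is UMI counts per gene and cell barcode without normalization, written by Cell Ranger 4.0.0 per the file headers. The submitters' processing notes also name Seurat 4.0.5 and the genome builds mm10 and GRCh38 without saying what each was used for. The deposited barcodes had been filtered before deposit, since the smallest barcode total was 500 UMIs in both libraries. The features numbered 32285, every 1 of the 345 listed genes was found among them, and none was named for tdTomato or a vector, so reporter and vector transcripts were not analysed here.

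Cells with at least 300 genes and at most 20% mitochondrial UMIs were kept, which left out 429 barcodes of the Muller and 905 of the MullerControl library. Doublets were scored per library with Scrublet as implemented in scanpy 1.11.5, and the cells with the highest scores were removed, 0.8% for each 1000 barcodes, or 1130 cells (9.51%) and 866 cells (8.32%). The automatic threshold of Scrublet called 803 and 3 cells, and with 3 of 10404 it did not work in the MullerControl library. Kept cells numbered 10757 and 9538, with 22152671 and 19983773 UMIs and medians of 1500 and 1587 UMIs per cell. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, a shared-nearest-neighbour graph over 15 neighbours and the Leiden algorithm (leidenalg 0.10.2, igraph 0.11.9) at resolution 1 gave 26 clusters over both libraries together. No integration between libraries was applied, because library and group are the same contrast. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

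Clusters were named from 17 marker lists by a rule. A cluster took the name of the list with the largest share of its markers at least 2-fold above the other cells (10 CPM added to both sides), with at least 3 such markers. It lost the name where its 10 leading genes held more markers of another list, or where its cells' UMIs lay, at the median, more than 3 times below the median of their library and no leading gene was a marker. Cluster 1, with a median of 682 UMIs against library medians of 1500 and 1587, lay above that limit and kept the rod name with 4 of 13 markers and none among its leading genes. Of the rule, 2 details were set after the data were seen: markers and leading genes were read only among genes detected in at least 5% of the cluster's cells, and a cluster in which another list also reached 60% of its markers stayed unnamed. The rule named 23 clusters and left 3 unnamed, with 2.48% of the Muller and 1.39% of the MullerControl cells. Clusters rebuilt in this way may differ in number and name from those of the study. Müller-like cells were those of clusters 3, 6 and 12.

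For each class with at least 50 cells in both libraries, UMIs were summed over its cells within each library and expressed as counts per 1000000 (CPM) of that sum, with exact Poisson 95% intervals. The log2 ratio, Muller over MullerControl, had 1 count added to each sum. Shares of cells have exact binomial (Clopper-Pearson) 95% intervals. A count of 0 was given the upper limit of 3 counts. Intervals cover counting error only, and no p-value was computed, since cells of 1 library are not replicates. Summed UMIs of the Müller-like class were 2254664 and 1888997, and the median log2 ratio over the 4088 genes eligible for naming was -0.03.

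Gene lists numbered 23, and they, the marker lists and the rule for named genes were written before the data were examined, from general knowledge of the retina and not from this study. A list member was measured with at least 20 UMIs over both libraries in the class. A list's median was set beside 10000 random lists of the same size matched on mean expression, drawn among the 100 nearest genes, and its percentile describes these libraries and is not a test between groups. A count of members at least 1.5-fold higher or lower describes the ratios alone. Named genes were those with at least 100 UMIs over both libraries in the class and at least 50 CPM in 1 of them, the 12 highest and 12 lowest ratios for Müller-like cells and the 4 highest and 4 lowest for each other class, plus up to 4 members per list with the largest absolute ratio. Ptbp1, Atoh7, Pou4f2, Sox9, Rbpms and Rlbp1 were named in every case. Outside the rule, the list members Glul, Kcnj10, Vim and Eif2s3y in Müller-like cells, Egr1, Tyrobp and C1qa in microglia-like cells and the leading genes of clusters were named after their values were seen. For the detection of RGC genes, cells were thinned at random to 1000 UMIs, which left out 515 and 275 Müller-like and 2391 and 2027 rod-like cells. The deposited gene identifiers were ENSMUSG00000006498 for Ptbp1, ENSMUSG00000036816 for Atoh7, ENSMUSG00000031688 for Pou4f2, ENSMUSG00000000567 for Sox9, ENSMUSG00000031586 for Rbpms, ENSMUSG00000039194 for Rlbp1, ENSMUSG00000026822 for Lcn2 and ENSMUSG00000004630 for Pcp2. Gene positions are from GENCODE M21 on GRCm38, the assembly that mm10 names; the annotation release behind the deposited counts is not stated.

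The procedure was tested on simulated data made from these counts. Planted fold changes of 1.5, 2, 4 and 0.5, with true log2 ratios of 0.56, 0.97, 1.97 and -1.03, were returned with medians of 0.56, 0.95, 2.01 and -0.99, and their intervals held the true value for 92%, 94%, 96% and 96% of 50 genes each. The summed counts were drawn with Poisson error alone. These values therefore do not show that the intervals hold for genes whose UMIs lie in few cells. Among 200 unchanged lists of 13 genes, 6% fell outside the 95% range. Simulated cells of 6 classes were named correctly in 300 of 300 cases each, and 44 of 50 planted RGC-like cells, drawn from an assumed profile, were found as RGC-like. The 6 classes were drawn from the mean profiles of cells that the rule had already named, so this does not test whether the names are right. The assumed profile held all 14 RGC genes at the same level and no amacrine marker. It does not measure how well rarer RGCs, or RGCs with fewer of these genes, would be found. In a first run the simulated bipolar-like cells were not named, because 1 cell rich in hemoglobin was spread over their mean profile; cells with at least 5% hemoglobin UMIs were then left out of the simulation, and the naming rule was not changed.

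Alternatives set before the data were examined numbered 13: a strict cell filter (500 genes, 10% mitochondrial UMIs), no cell filter, no doublet removal, the automatic Scrublet threshold, Leiden resolutions of 0.5 and 2, clustering each library on its own, means over cells, scaling by the median ratio, leaving out mitochondrial and rod genes, using the Müller-like cells with fewer rod UMIs, a minimum of 100 UMIs for list members and thinning to 2000 UMIs. Another 5 were added after the data were seen: the Müller-like cluster with the highest median UMI count alone, Müller-like clusters weighted equally, shares among cells that are not rod-like, single genes in Müller-like cells without the cell that held at least 40% of their UMIs in a library, and the named genes of bipolar-like cells without cluster 22. A gene with fewer than 20 UMIs over both libraries under an alternative, or within a single cluster, was given no ratio there, a rule for these ratios set after the data were seen. Log2 ratios and list medians within single clusters were also taken after the data were seen.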

Results

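Retinal cells were taken from mice carrying a Cre-dependent tdTomato reporter 8 weeks after injection of an adeno-associated virus (AAV), tdTomato-positive cells were sorted, and their transcripts were counted in single droplets as unique molecular identifiers (UMIs). The series title concerns the conversion of Müller cells, the principal glia of the retina, to retinal ganglion cells (RGCs), the neurons whose axons form the optic nerve. The library labelled Muller was taken as the test virus and the library labelled MullerControl as the control virus; the labels do not say what the test virus carried or how many mice were pooled. Each group had 1 library. There were no replicates and no test between groups, and every interval given is a 95% interval for counting error alone, without the variation between mice, injections, sorts or libraries. Intervals of summed UMIs also leave out the variation between cells. Leaving out 1 cell moved the ratios of Lcn2, Igfbp7 and Rsad2, given below, beyond their own intervals. The same held for Snhg11, whose log2 ratio went from 2.93 (2.25 to 3.61) to 3.85. The Muller library held 12316 barcodes and 25622379 UMIs, with a median of 1478 UMIs and 853 genes per barcode. The MullerControl library held 11309 barcodes and 23549118 UMIs, with a median of 1552 UMIs and 825 genes. After filtering and doublet removal, 10757 and 9538 cells were kept.

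The first question was which cell classes the sorted cells of each library belonged to. Whether each cell carried the reporter could not be checked, since no feature was named for tdTomato. Rod-like cells, the photoreceptors of dim light, were the most frequent class in both libraries, at 41.75% of kept cells in the Muller library (40.8% to 42.7%) and 66.5% in the MullerControl library (65.6% to 67.5%). Their clusters did not move together: clusters 0 and 2 had share ratios of 0.487 and 0.316, but cluster 1, with a median of only 682 UMIs per cell and no rod marker among its 10 leading genes, had 1.52 and held 47.5% of the rod-like cells of the Muller library against 19.6%. Bipolar-like cells, the interneurons that pass photoreceptor signals to the inner retina, took 30.9% (30.03% to 31.8%) against 10.3% (9.69% to 10.9%). Amacrine-like cells, inhibitory interneurons of the inner retina, took 8.30% (7.79% to 8.84%) against 2.33% (2.03% to 2.65%), a share ratio of 3.57 (3.09 to 4.12). Müller-like cells made up 11.8% (11.2% to 12.4%) and 8.16% (7.62% to 8.72%), or 1269 and 778 cells.

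Cone-like cells, the photoreceptors of daylight and colour vision, were less frequent in the Muller library, at 3.63% (3.28% to 4.00%) against 9.42% (8.84% to 10.0%), a share ratio of 0.385 (0.343 to 0.432). Microglia or macrophage-like cells, the resident and infiltrating phagocytes, stood at 1.05% (0.867% to 1.26%) and 1.79% (1.54% to 2.08%). A small cluster with markers of the retinal pigment epithelium held 10 and 7 cells. No cluster was named as RGC-like, horizontal-like or astrocyte-like. Clusters left without a name held 2.48% and 1.39% of the cells, and 1 of them, with 185 and 37 cells, carried markers of both horizontal and amacrine cells.

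The larger amacrine-like share came from both amacrine-like clusters. Cluster 15, with Gad1, Gad2, C1ql1, C1ql2 and Tfap2b among its leading genes and so of GABAergic type, held 345 cells (3.21%) of the Muller library and 18 cells (0.189%) of the MullerControl library. Cluster 5, with Slc6a9, the glycine transporter, and the transcription factor Ebf3 among its leading genes, held 548 and 204 cells, a share ratio of 2.38 (2.03 to 2.79). It raised 5 of the 10 amacrine markers and 5 of the 14 RGC markers, Ebf3 being 1 of the latter, and took the amacrine name by the larger share of its list. Cluster 15 raised 7 of the 10 amacrine markers. It was nearly all from 1 library, so its standing apart as a cluster of its own may reflect that library. Of the 11 bipolar-like clusters, cluster 17 showed the highest share ratio, at 7.22 (4.88 to 10.7), and cluster 22, with 55 and 91 cells, the lowest, at 0.536 (0.384 to 0.748).

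All of these are shares of sorted cells, and the tdTomato-positive rate before the sort was about 4.9% for the test group and 10% for the control group. Because rod-like cells dominated, the shares were also taken among the cells that were not rod-like, 6266 and 3191, a setting chosen after the data were seen. The amacrine-like share ratio was then 2.05 (1.78 to 2.36) and the bipolar-like ratio 1.72 (1.63 to 1.82), but the Müller-like ratio turned to 0.831 (0.768 to 0.898), so the direction for Müller-like cells depended on the denominator. With each library clustered on its own the Müller-like ratio over all kept cells was 2.74, and at a Leiden resolution of 2 the amacrine-like ratio was 6.85. The bar chart of class shares gives the values over all kept cells.

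**Figure D1:**
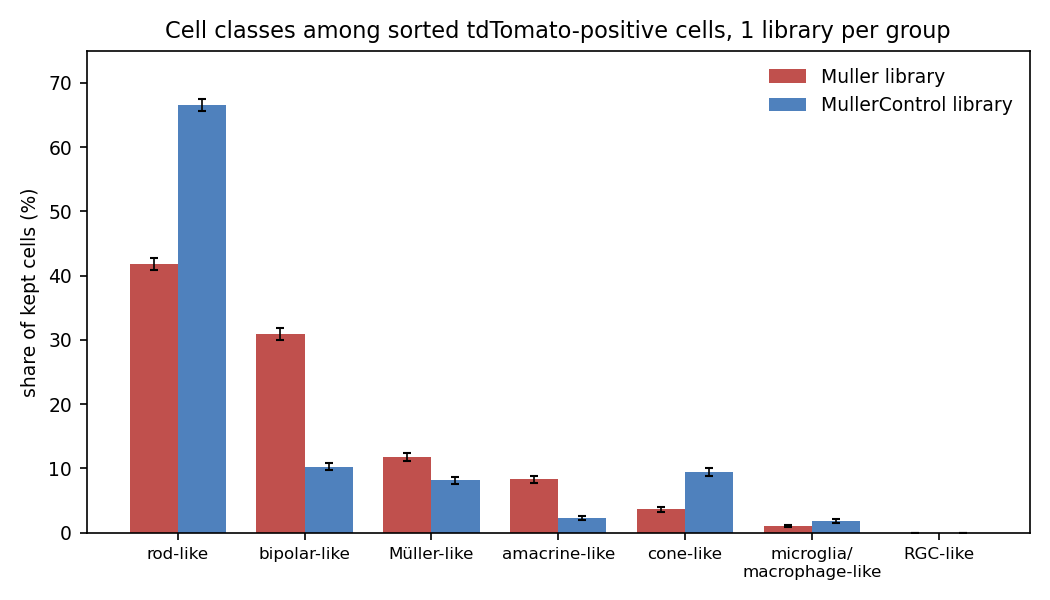
Share of kept cells in each class (vertical axis, percent) for the Muller library (red) and the MullerControl library (blue), with 1 library per group and error bars for the exact 95% binomial interval. Bipolar-like cells stand at 30.9% and 10.3%, rod-like cells at 41.75% and 66.5%, and RGC-like cells at 0 in both libraries.

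The next question was whether RGC-like cells were present among the sorted cells. Pou4f2, a transcription factor of most RGCs (chromosome 8, 78433010 to 78436645 on GRCm38), and its relative Pou4f3 (chromosome 18, 42394539 to 42397249) had 0 UMIs in either library over every deposited barcode. Pou4f1 (chromosome 14, 104461676 to 104467999) had 0 UMIs in the Muller library and 3 in the MullerControl library. A count of 0 allows up to 0.0244% of barcodes with a UMI in the Muller library and 0.0265% in the MullerControl library. No cluster was named RGC-like among the 10757 and 9538 kept cells. The smallest named cluster held 17 cells, so a smaller number of RGCs may not form a cluster and is not excluded by the naming.

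Other genes of the RGC list were detected. Slc17a6, the vesicular glutamate transporter of RGCs, had 11 UMIs in the Muller library and 15 in the MullerControl library, and Rbpms, an RNA-binding protein used as a pan-RGC marker, had 101 and 113. Of the kept cells with Slc17a6, 6 of 9 in the Muller and 13 of 13 in the MullerControl library were cone-like. The 3 MullerControl cells with Pou4f1 were cone-like as well. Other genes of the list were more abundant in the Muller library, with 488 against 136 UMIs for the neurofilament gene Nefl, 217 against 37 for Nefm, 67 against 17 for the synuclein gene Sncg, 289 against 117 for Gap43, 760 against 401 for Thy1 and 607 against 464 for Ebf3. Nefh, at 295 and 331 UMIs, Nrn1, at 21 and 33, and Rbpms2, at 31 and 38, were not. Amacrine-like cells numbered 893 in the Muller and 222 in the MullerControl library. They were 161 of 232 and 53 of 73 kept cells with Nefl, and 258 of 314 and 140 of 167 with Ebf3. With Gap43 they were 71 of 174 and 18 of 76, and with Sncg 2 of 26 and 0 of 8. Among amacrine-like cells Nefl was seen in 18.0% and 23.9%, Thy1 in 29.0% and 52.3% and Ebf3 in 28.9% and 63.1%. Nefm was seen in 7.28% and 6.31% of them, and Gap43 in 7.95% and 8.11%. The bar chart of RGC genes over all barcodes shows the UMI counts relative to the size of each library.

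**Figure D2:**
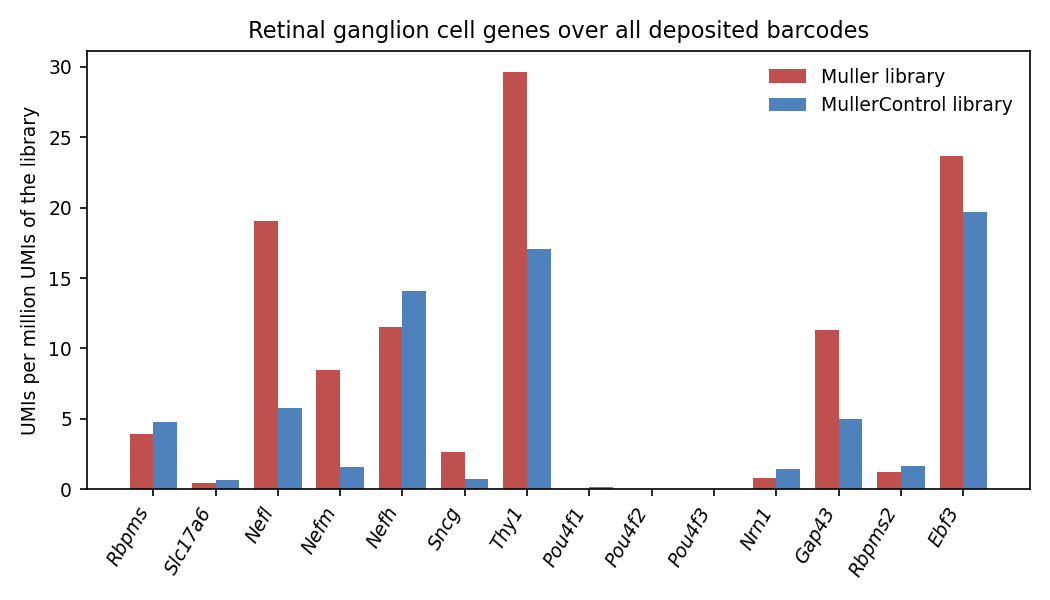
UMIs of 14 RGC genes per 1000000 UMIs of the library (vertical axis), over all deposited barcodes of the Muller library (red) and the MullerControl library (blue), with 1 library per group and no error bars. Nefl stands at 19.0 and 5.78 and Thy1 at 29.7 and 17.0, while Pou4f2 and Pou4f3 are at 0 in both libraries.

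Cells with UMIs of at least 4 of the 14 RGC genes numbered 30 of 10757 in the Muller library (0.279%, 0.188% to 0.398%) and 7 of 9538 in the MullerControl library (0.0734%, 0.0295% to 0.151%). Amacrine-like clusters held 27 and 6 of them, which was 3.02% and 2.70% of the amacrine-like cells, and Müller-like clusters held 0 of 1269 and 0 of 778. Over the 37 cells, Nefl was seen in 36, Nefm in 32, Thy1 in 32 and Ebf3 in 31, whereas Pou4f1, Pou4f2 and Pou4f3 were seen in 0. Nefh was seen in 9, Sncg and Gap43 in 4 each, and Rbpms, Slc17a6, Rbpms2 and Nrn1 in 1 each. The highest number in 1 cell was 7 of the 14, in an amacrine-like cell of the Muller library. The naming of whole clusters does not exclude single RGCs among these cells.

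RGC genes were then counted in Müller-like cells at equal depth, with each cell thinned to 1000 UMIs and shallower cells left out. Cells with at least 2 RGC genes numbered 4 of 754 in the Muller library (0.531%, 0.145% to 1.35%) and 2 of 503 in the MullerControl library (0.398%, 0.0482% to 1.43%). Rod-like cells, taken as a reference for free RNA, had 0 of 2100 and 0 of 4320, which allows up to 0.143% and 0.0694%. They are not free of the list's transcripts, since Nefh was seen in 1.24% and 1.41% of them and in 0 of 754 and 0 of 503 Müller-like cells. Their median depth before thinning was lower, at 1536 and 1667.5 UMIs against 2122 and 3023 in the Müller-like cells. Without thinning the Müller-like values were 10 of 1269 (0.788%) and 15 of 778 (1.93%), in the order of the median depths of 1291 and 1549 UMIs. Rbpms was seen in 2.52% (1.52% to 3.91%) and 2.78% (1.53% to 4.63%) of thinned Müller-like cells, against 0.0952% and 0.116% of rod-like cells, so its transcripts exceeded the level in rod-like cells in both libraries. No difference between the libraries was detectable at this depth.

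Müller-like cells formed clusters 3, 6 and 12, and their UMIs were summed within each library to compare expression. The glial identity genes were present at high levels in both libraries. Sox9, a transcription factor of glia (chromosome 11, 112782224 to 112787760), stood at 381 counts per 1000000 UMIs (CPM), with an interval of 356 to 407, in the Muller library and 382 CPM (355 to 411) in the MullerControl library, a log2 ratio of -0.005 (-0.15 to 0.14). Rlbp1, the retinaldehyde-binding protein of the visual cycle (chromosome 7, 79374870 to 79387048), stood at 1735 CPM (1681 to 1790) and 2318 CPM (2250 to 2388), a log2 ratio of -0.42 (-0.48 to -0.36). Ptbp1, a repressor of neuronal splicing (chromosome 10, 79854427 to 79864771), stood at 50.1 CPM (41.3 to 60.3) from 113 UMIs and 69.3 CPM (58.0 to 82.3) from 131 UMIs, a log2 ratio of -0.47 (-0.83 to -0.11). In rod-like cells Ptbp1 stood at 24.2 and 23.7 CPM and in bipolar-like cells at 31.2 and 30.5 CPM.

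Atoh7, the proneural factor required for RGC genesis (chromosome 10, 63099651 to 63101279), and Pou4f2 had 0 UMIs in Müller-like cells of either library, which allows up to 1.33 CPM in the Muller library and 1.59 CPM in the MullerControl library. Atoh7 was counted in cone-like cells at 30.8 CPM (21.2 to 43.2) and 29.5 CPM (23.8 to 36.1). Rbpms stood at 26.6 CPM and 30.2 CPM in Müller-like cells, a log2 ratio of -0.18 (-0.70 to 0.34).

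The makeup of the Müller-like class differed between the libraries. Cluster 12, with the deepest cells at medians of 4125 and 5070.5 UMIs, held 16.6% of the class in the Muller library and 30.1% in the MullerControl library, and with them 39.8% and 63.1% of the summed UMIs. Cluster 6, in which the nuclear transcript Malat1 reached 229768 and 165327 CPM, held 39.7% and 19.8%, and cluster 3, with Malat1 at 15321 and 4703 CPM, held 43.7% and 50.1%. The median mitochondrial share of a cell was 3.11% against 4.84% in cluster 3, 1.15% against 2.43% in cluster 6 and 0.519% against 0.491% in cluster 12, so these marks of RNA quality also differed between the libraries. Within single clusters, a comparison chosen after the data were seen, the log2 ratio of Ptbp1 was 0.43 (-0.42 to 1.29) in cluster 3, -1.34 (-2.17 to -0.51) in cluster 6 and -0.20 (-0.67 to 0.26) in cluster 12, so the sign of the estimate differed between the clusters, with intervals in clusters 3 and 12 that include 0. That of Rlbp1 was -0.04, -0.59 and -0.14, and that of Sox9 0.53, -0.11 and 0.16.

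Neuronal genes were higher in the Müller-like cells of the Muller library. Of 13 measured genes of a pan-neuronal list, 10 were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 1.21 (0.91 to 1.68), above the middle 95% of 10000 random lists matched on expression (-0.21 to 0.18). Examples were Snhg11 at 76.3 against 9.53 CPM, with 50% of its 18 MullerControl UMIs in 1 cell and 4.77 CPM without it, Uchl1 at 20.4 against 3.18 CPM and Stmn3, a tubulin-binding protein of neurons, at 39.0 against 6.88 CPM. In rod-like cells the median of the same list was 1.79 over 16 measured genes, and 1.08, 1.47 and 0.69 within rod-like clusters 0, 1 and 2, so the excess was not particular to Müller-like cells. The Müller-like median was 0.75 in cluster 12 alone and 0.67 with the automatic Scrublet threshold.

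Among single genes, 10 of the 12 with the highest ratio in Müller-like cells, all but Lcn2 and Xist, are expressed by neurons, bipolar cells among them. Pcp2, a bipolar cell gene (chromosome 8, 3623371 to 3625545), stood at 263 CPM (242 to 285) against 47.6 CPM (38.3 to 58.6), a log2 ratio of 2.45 (2.13 to 2.77), and in rod-like cells its log2 ratio was 2.92. Neurod4, a proneural transcription factor, had a log2 ratio of 2.72 (1.95 to 3.50) in Müller-like and 2.43 in rod-like cells, Pcp4 2.61 (2.11 to 3.12) and 2.51, and Trpm1, the transduction channel of ON bipolar cells, 1.91 (1.42 to 2.41) and 2.19. The log2 ratios of Snhg11, Nap1l5, Gng13, Trnp1, Scg2 and Cplx3 lay between 1.65 and 2.93 in Müller-like cells, and between 1.89 and 3.24 in rod-like cells. All 10 kept their direction in the alternatives, but the size moved, from 1.20 to 3.78 for Pcp2, 1.02 to 3.09 for Neurod4, 1.83 to 3.44 for Pcp4, 0.90 to 2.58 for Trpm1, 0.93 to 3.09 for Gng13 and 0.46 to 2.40 for Cplx3. The automatic Scrublet threshold, which removed 803 and 3 cells, gave 1.20 for Pcp2, 1.02 for Neurod4 and 0.90 for Trpm1. All 11 measured genes of the bipolar marker list were at least 1.5-fold higher in Müller-like cells, as were 11 of 12 in rod-like and 9 of 11 in cone-like cells. The median log2 ratio was 2.39 in Müller-like, 2.41 in rod-like, 1.93 in cone-like and 1.91 in microglia-like cells, and 1.35 over 5 genes in Müller-like cluster 12 alone. Within rod-like clusters 0, 1 and 2 it was 2.45, 1.77 and 2.11. The amacrine marker list had a median of 3.40 in Müller-like and 4.04 in rod-like cells.

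Lcn2, which encodes the secreted siderophore-binding protein lipocalin 2 and marks reactive glia (chromosome 2, 32384633 to 32388252), had the highest ratio among the genes abundant enough to be ranked, at 64.3 CPM (54.3 to 75.7) against 7.94 CPM (4.44 to 13.1) and a log2 ratio of 2.93 (2.19 to 3.68). Of its 145 UMIs in the Muller library, 52.4% came from 1 cell, and without that cell, a setting chosen after the data were seen and used below for other genes, the log2 ratio was 1.88 (1.09 to 2.66). In cluster 12 alone, where 71.0% of the 107 UMIs were in 1 cell, it was 4.36. Lcn2 was detected in 25 of 1269 and 11 of 778 Müller-like cells, or 1.97% and 1.41%. Xist, the X-inactivation transcript, had a log2 ratio of 1.66 (1.51 to 1.81) in Müller-like and 1.56 in rod-like cells.

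**Figure D3:**
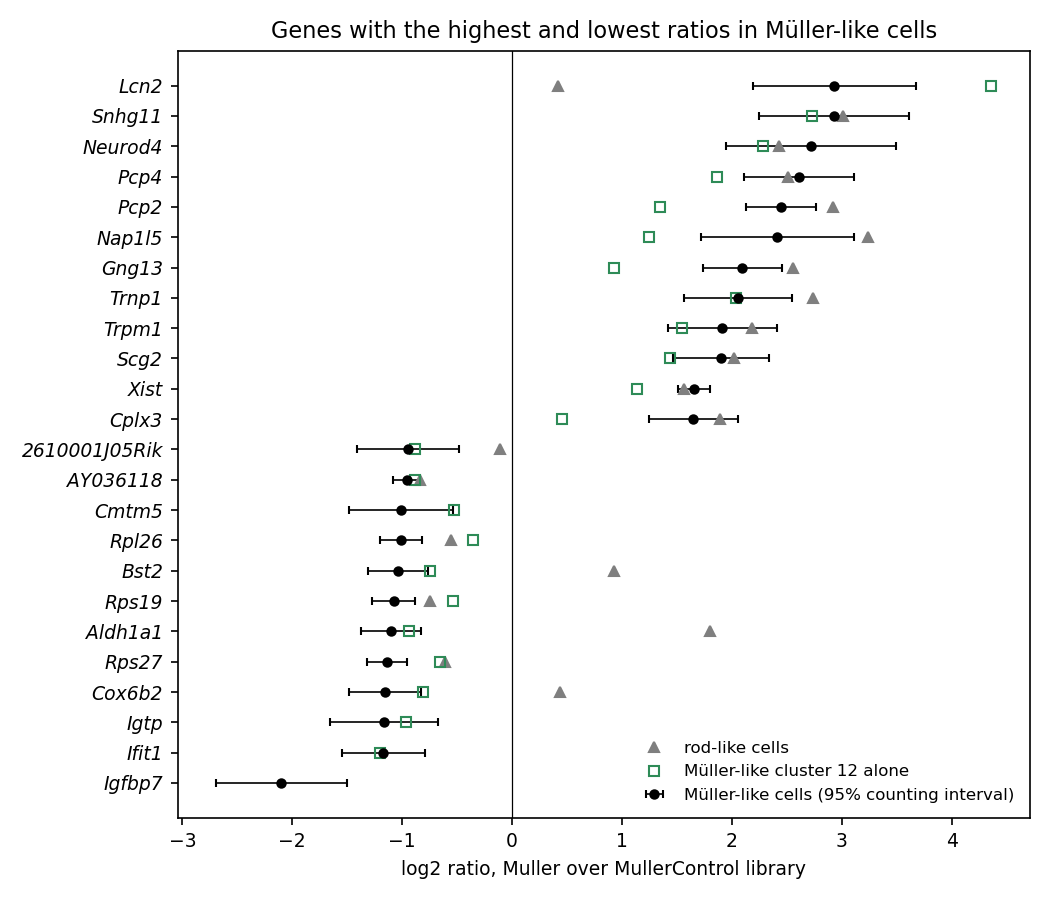
Log2 ratio, Muller over MullerControl library (horizontal axis), for the 12 genes with the highest and the 12 with the lowest ratio in Müller-like cells, with 1 library per group. Black points are Müller-like cells with their 95% counting interval, open squares are Müller-like cluster 12 alone and triangles are rod-like cells; Pcp2 stands at 2.45 in Müller-like and 2.92 in rod-like cells, and Lcn2 at 2.93 and 0.42.

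Interferon-induced genes were lower in the summed Müller-like cells of the Muller library. Of 12 measured genes of the interferon list, 6 were at least 1.5-fold lower and 0 higher, with a median log2 ratio of -0.51 (-0.79 to -0.31), under the random range of -0.20 to 0.15. Ifit1, an inhibitor of viral RNA translation, stood at 38.1 against 86.3 CPM, a log2 ratio of -1.17 (-1.54 to -0.79), Bst2, the restriction factor tetherin, at -1.04 (-1.31 to -0.76), and Rsad2, which encodes viperin, at -1.68 (-2.30 to -1.07). Of the Rsad2 UMIs of the MullerControl library 45.5% came from 1 cell, and without that cell the log2 ratio was -0.83 (-1.51 to -0.15). Most UMIs of Ifit1 were in cluster 12, with 48 against 149, whereas cluster 3 had 15 against 4. Cxcl10 had 0 UMIs in the Muller library and 52 in the MullerControl library, at least 20.7-fold lower against a floor of 3 counts, but 88.5% of the 52 came from 1 cell. In cluster 12 alone the list median was -0.53. The list went the other way in rod-like cells, with a median of 1.53 and 6 of 8 genes higher, and in bipolar-like cells, with 0.60 and 4 of 8 higher, both above their random ranges. Levels in rod-like cells were low, with Ifit1 at 10 against 5 UMIs and Bst2 at 9.41 against 4.95 CPM. The Müller marker list was higher too, at 1.79 in rod-like and 1.30 in bipolar-like cells. Free Müller RNA therefore cannot be told apart from expression of interferon genes in these cells. Within rod-like clusters 0, 1 and 2, where only 5, 5 and 3 interferon genes were measured, the median of the interferon list was 0.23 (-0.04 to 1.12), 0.32 (-0.09 to 1.17) and 0.39 (0.0089 to 0.79). With the clusters weighted equally, a setting chosen after the data were seen, the median was -0.0021, at percentile 57.6, so the difference in Müller-like cells depended on how the clusters were weighted.

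Genes of Müller homeostasis stood slightly lower. Of 13 measured genes, 0 passed 1.5-fold in either direction, and their median log2 ratio was -0.34 (-0.38 to -0.26), under the random range of -0.26 to 0.05. The glutamine synthetase gene Glul stood at 8335 against 10191 CPM, Rdh10, a retinol dehydrogenase, at 145 against 214 CPM, and Kcnj10, the main potassium channel of Müller cells, at 187 against 237 CPM. In cluster 12 alone the median was -0.20, at percentile 0.26, and with equal cluster weights it was -0.19, at percentile 8.52. In rod-like cells it was 0.97.

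The remaining genes with the lowest ratio were Igfbp7 at a log2 ratio of -2.10 (-2.69 to -1.50), with 50.5% of its MullerControl UMIs in 1 cell, -1.10 (-1.75 to -0.44) without that cell and 0.37 under a strict cell filter, the interferon-induced GTPase gene Igtp at -1.17, Cox6b2 at -1.16, the ribosomal protein genes Rps27 at -1.14, Rps19 at -1.07 and Rpl26 at -1.01, Aldh1a1, an enzyme of retinoic acid synthesis, at -1.10 (-1.37 to -0.83), Cmtm5 at -1.01, AY036118 at -0.96 and 2610001J05Rik at -0.95. AY036118 and the ribosomal genes were also lower in rod-like cells, with AY036118 at -0.83 and Rps27 at -0.61, whereas Aldh1a1 was higher there, at 1.80. The ribosomal genes depended on the processing: in cluster 12 alone Rps27 stood at -0.65, Rps19 at -0.54 and Rpl26 at -0.35, and with each library clustered on its own at -0.43, -0.37 and -0.063.

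The reactive gliosis list did not move as a group. Of 11 measured genes 2 were at least 1.5-fold higher, Lcn2 and the cytokine signalling inhibitor Socs3 (18.6 against 7.41 CPM, log2 ratio 1.26, 0.42 to 2.11), 0 were lower, and the median was -0.04, inside the random range of -0.24 to 0.17. The intermediate filament gene Vim stood at 969 and 1049 CPM. The 13 genes that keep glia quiescent had a median of -0.11, inside the random range, with the Notch target Hes5 at -0.44 (-0.61 to -0.27) and Sox8 at 0.39 (0.20 to 0.58).

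Of 9 measured retinogenic factors, 3 were higher, namely Neurod4, Isl1 at 2.05 (1.22 to 2.87) and Insm1 at 0.94 (-0.34 to 2.22), and the list median of 0.29 lay inside the random range of -0.27 to 0.33. In rod-like cells 3 of 10 measured factors were higher and 1 lower, with a median of -0.01. In cone-like cells 3 of 9 were higher and 0 lower, with a median of 0.18, so this count was not particular to Müller-like cells. Only 4 of the 14 RGC genes had enough UMIs in Müller-like cells, and their median log2 ratio of -0.53 lay under the random range of -0.42 to 0.45, with Gap43 at -0.74 (-1.42 to -0.06), Rbpms2 at -0.62 (-1.63 to 0.39) and Thy1 at -0.44 (-0.88 to 0.01). In cluster 12 alone only 2 RGC genes were measured, with a median of -0.10, inside the range of -0.62 to 0.64. In rod-like cells 5 of 6 measured RGC genes were higher, with a median of 2.04; within rod-like clusters 0, 1 and 2 only 2, 1 and 2 of them were measured, with medians of 1.38, 2.69 and 0.75. The 4 genes of the polypyrimidine tract-binding and REST list had a median of -0.10, with Ptbp3 at 0.55 (0.04 to 1.06) but -0.35 in cluster 12 alone, Ptbp2 at -0.18 (-0.47 to 0.11) and Rest at -0.01 (-0.26 to 0.23).

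**Figure D4:**
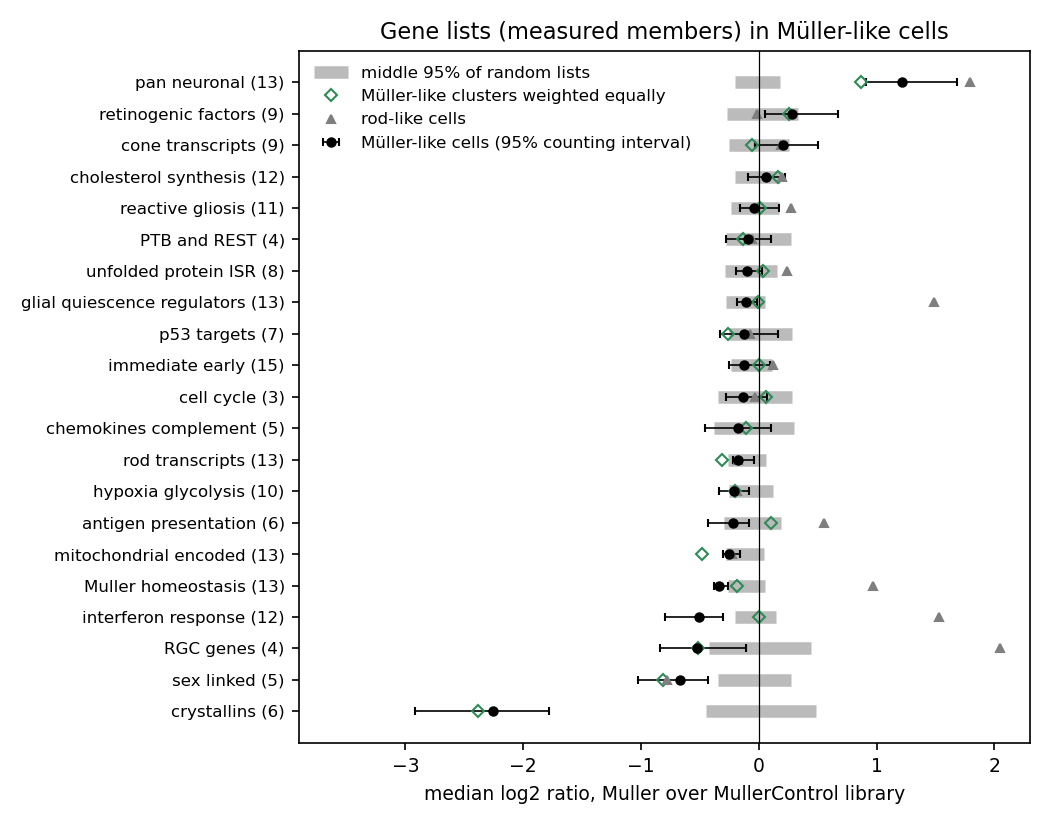
Median log2 ratio of each gene list with at least 3 measured genes, Muller over MullerControl library (horizontal axis), with the number of measured genes after each name and 1 library per group. Black points are Müller-like cells with their 95% counting interval, diamonds are the Müller-like clusters weighted equally, triangles are rod-like cells and grey bars are the middle 95% of random lists; the interferon list moves from -0.51 to -0.0021 with equal weights, and the pan-neuronal list stands at 1.21 in Müller-like and 1.79 in rod-like cells.

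Stress and metabolic lists lay inside their random ranges in the summed Müller-like cells. Median log2 ratios were -0.13 for 15 immediate early genes, among which Egr1 stood at 0.81 (0.50 to 1.12) and Hspa1b at -1.01 (-1.77 to -0.24), -0.10 for 8 genes of the unfolded protein response, -0.13 for 7 targets of p53, -0.13 for 3 cell cycle genes, -0.21 for 10 genes of hypoxia and glycolysis and 0.06 for 12 genes of cholesterol synthesis. Antigen presentation had a median of -0.22 over 6 genes, 1 of them lower, B2m at -0.65 (-0.84 to -0.47). The 13 mitochondrially encoded genes had a median of -0.25, and the chemokine and complement list -0.17 over 5 genes, of which Cxcl10 was lower. Rod transcripts, with a median of -0.18 over 13 genes, and cone transcripts, with 0.20 over 9 genes and 2 higher, Gnb3 and Gngt2, also lay inside their ranges. Some of these depended on the clusters taken. With equal cluster weights the mitochondrially encoded genes had a median of -0.48, under the range of -0.28 to 0.12, with 5 of them lower, and rod transcripts a median of -0.31, under -0.26 to 0.11. In cluster 12 alone rod transcripts stood at 0.17, just above the range of -0.19 to 0.16, and cone transcripts at 0.58, above -0.48 to 0.36.

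A few lists rested on very few cells or genes. Of 6 measured crystallins 3 were lower, at a median of -2.26, or -1.84 with genes at 0 set to their bound, but the UMIs of Crygs, Cryaa and Crybb2 came from 3 MullerControl cells each. Crygs was at least 9.95-fold and Cryaa at least 9.15-fold lower against the floor, and Crybb2 had 2 against 40 UMIs, a log2 ratio of -4.03 (-5.72 to -2.34). Under a strict cell filter and in cluster 12 alone none of these UMIs were left except 1 of Crybb2 in the Muller library, so no ratio could be taken there. The astrocyte list had 1 measured gene, S100b, at -1.14 (-1.94 to -0.33), and the microglia list 2, C1qa at 2.20 (0.67 to 3.74) and Ctss at 1.16 (-0.19 to 2.51). Of the 5 sex-linked genes Xist was higher and the Y-linked genes Kdm5d, Uty, Ddx3y and Eif2s3y were lower, at -1.23, -1.15, -0.67 and -0.60.

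The neuronal classes were compared in the same way. In rod-like cells the genes with the highest ratio were Pnmal2 at a log2 ratio of 3.42 (2.96 to 3.88), the tubulin gene Tubb2a at 3.30 (2.90 to 3.70), Nap1l5 at 3.24 (2.89 to 3.59) and the imprinted transcript Meg3 at 3.02 (2.69 to 3.35). Of these, Pnmal2, Tubb2a and Meg3 were more abundant in Müller-like cluster 12 than in rod-like cells in both libraries, with Tubb2a at 252 and 254 CPM against 61.3 and 6.13 CPM. Levels in the other classes were not compared, so this does not show where these transcripts came from. The lowest in rod-like cells were the beta-globin gene Hbb-bs at -6.18 (-7.60 to -4.76), with 3 against 518 UMIs, AY036118, Ddx3y at -0.78 and Lbh at -0.77. In cone-like cells the highest were Scg2 at 3.16 (2.56 to 3.75), Pcp4 at 2.91 (2.42 to 3.39), Trpm1 at 2.77 (2.17 to 3.37) and Pcp2 at 2.77 (2.43 to 3.11), and each of these was also among the highest in Müller-like cells. Over the alternatives their ratios in cone-like cells went down to 1.69, 1.42, 1.19 and 1.37. The lowest in cone-like cells were the Y-linked Eif2s3y at -1.70 and Ddx3y at -1.34, Ino80d at -1.42 and 5430419D17Rik at -1.36.

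In bipolar-like cells the highest ratios were those of the globin genes Hbb-bs at 8.11, Hba-a1 at 7.39, Hba-a2 at 6.58 and Hbb-bt at 6.01, with between 99.9% and 100% of the UMIs of each in 1 cell; under a strict cell filter, with 2 UMIs of Hbb-bs in each library, no ratio could be taken. Over all classes, 1 cell held 99.9% of the globin UMIs of the Muller library, and 2 cells held 84.2% of those of the MullerControl library. Bipolar-like cells had their lowest ratios in Cpne9 at -2.29, Tshz2 at -2.05, Lrp1b at -1.79 and Csmd3 at -1.72, which are leading genes of cluster 22. Without that cluster, a setting chosen after the data were seen, the log2 ratios were 0.28 (-0.47 to 1.04) for Tshz2, -0.46 (-0.89 to -0.03) for Lrp1b and -0.68 (-1.05 to -0.31) for Csmd3, and Cpne9 had too few UMIs left. In amacrine-like cells C1ql1 at 5.20, Maf at 3.95, Id4 at 3.35 and Ccdc88b at 3.12 were highest. The alternatives gave lower ratios in every case for C1ql1 (2.75 to 4.45) and Ccdc88b (2.15 to 2.73), and 2.87 to 4.18 for Maf and 2.58 to 3.59 for Id4. Within cluster 15 alone, again looked at after the data were seen, with 9 or fewer UMIs of each in the MullerControl library, C1ql1 stood at 3.67 (2.77 to 4.56), Id4 at 1.53 (0.45 to 2.61) and Ccdc88b at 1.11 (0.15 to 2.07). Maf, with 211 against 0 UMIs there, stood at 4.08 (1.25 to 6.92). The lowest in amacrine-like cells were Gm42716 at -1.88, Traip at -1.86, the receptor gene Crhr1 at -1.72 and the cone opsin gene Opn1sw at -1.72. Within cluster 5 they stood at -1.52, -1.42, -1.21 and -2.31, in the same order. In cluster 15 only Opn1sw had enough UMIs, 64 against 1, and its log2 ratio there was 1.38 (-0.65 to 3.41), and 42.6% of its amacrine-like UMIs in the Muller library came from 1 cell.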

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

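Cluster 12 alone, Müller-like clusters weighted equally, shares among cells that are not rod-like, and single genes without the cell richest in them or without bipolar-like cluster 22 were chosen only after the data were seen, and the other settings before. No paired analysis was possible because each group had 1 library and nothing but the replicate number 1 joined them. No cluster was named RGC-like in either library under any of the 7 alternatives run for it. Of the alternative values, 31 of the share ratios stayed within their counting interval, 15 moved and 1 reversed, and for the list medians that answer a comparison 56 stayed and 12 moved. Medians of the other lists stayed in 173 cases, moved in 46 and reversed in 1. Log2 ratios of single genes stayed in 1366 cases, moved in 234 and reversed in 27, and 69 further values, of 28 genes, could not be given because fewer than 20 UMIs were left, among them the globin genes in bipolar-like cells under the strict filter. Few Müller-like cells have UMIs of RGC genes, and in a single cell low depth cannot be told apart from low or absent expression. The cause of the changes was not tested, apart from those that the smaller denominator or the choice of clusters makes by construction.

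Among cells that are not rod-like the share ratios were 0.831 for Müller-like (reversed), 2.05 for amacrine-like, 1.72 for bipolar-like, 0.221 for cone-like and 0.337 for microglia-like cells. With each library clustered on its own they were 2.74 for Müller-like, 2.86 for amacrine-like, 2.51 for bipolar-like and 0.752 for rod-like cells. The strict cell filter gave 1.76 for Müller-like, 3.64 for bipolar-like and 0.528 for rod-like cells. The bipolar-like ratio was 2.66 without a cell filter and 2.74 with the automatic Scrublet threshold, the rod-like ratio 0.595 without doublet removal, and the amacrine-like ratio 6.85 at a Leiden resolution of 2.

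The median log2 ratio of the homeostasis list was -0.43 without doublet removal, -0.49 with each library clustered on its own, -0.20 in cluster 12 alone and -0.19 with equal weights. The interferon list stood at -0.0021 with equal weights and kept its direction in each of the other alternatives. The pan-neuronal list stood at 0.67 with the automatic Scrublet threshold, 1.71 at both Leiden resolutions, 1.83 with each library clustered on its own, 0.75 in cluster 12 alone and 0.87 with equal weights. The reactive gliosis list stood at -0.25 without doublet removal. Müller-like cells of the MullerControl library with at least 2 RGC genes fell to 0% under the strict filter, without a filter and with each library clustered on its own.

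With each library clustered on its own, log2 ratios were 0.0091 for Cryab and for the crystallin list, 0.63 for Gnat1, 0.98 for Igfbp7, 0.69 for Pdc, 0.93 for Pde6a, 0.42 for mt-Atp6 and 0.16 for mt-Nd3. The strict filter gave 0.32 for Gnat1, 0.37 for Igfbp7, 0.33 for Pdc and 0.81 for Pde6a. In cluster 12 alone the values were 0.17 for Cryab, 0.38 for Pde6a and -0.35 for Ptbp3. At a Leiden resolution of 2 they were 0.052 for Gnat1, 0.056 for Pdc and 0.31 for Pde6a, and at 0.5 Pde6a stood at 0.19. In the Müller-like cells with fewer rod UMIs, Gnat1 stood at 0.49, Pdc at 0.52 and Pde6a at 1.05. Means over cells gave 0.035 for Bnip3 and 0.40 for Fosb. Pde6a stood at 0.089 without a cell filter, Tshz2 in bipolar-like cells at 0.28 without cluster 22, H2-K1 at 0.068 with equal weights and Rcvrn at -0.0062 with the automatic Scrublet threshold.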

Other observations

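Of the tests reported here, those of fewer rod-like cells alone, of the sex of the mice for bipolar-like cells, of Müller cells in transition, of the vectors or the sort, of doublets and of free RNA of Lcn2 were chosen only after the result was seen, as were the settings named as such. Microglia or macrophage-like cells, 113 in the Muller and 171 in the MullerControl library, differed in stress genes. Their depth differed too, with medians of 3567 and 4848 UMIs per cell. Of 15 immediate early and heat shock genes, 7 were at least 1.5-fold lower in the Muller library and 0 higher, with a median log2 ratio of -0.53, under the random range of -0.19 to 0.12. Atf3, a stress-induced transcription factor, stood at 194 against 560 CPM, a log2 ratio of -1.52 (-1.86 to -1.17). The heat shock genes Hspa1a at -1.43 (-1.62 to -1.24) and Hspa1b at -1.49 (-1.72 to -1.26), the phosphatase gene Dusp1 at -1.18 (-1.68 to -0.67) and Egr1 at -0.77 (-1.02 to -0.51) went the same way. In Müller-like cells Egr1 had the opposite sign, at 0.81, and this difference between classes was not tested.

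The 12 microglia markers themselves were level, with a median of 0.02, among them Tyrobp at 3516 and 3513 CPM and C1qa at 10217 and 9472 CPM. Cd74, the invariant chain of MHC class II, was higher, at 308 against 52.6 CPM, with 48.4% of its UMIs in 1 cell. The chemokine gene Ccl12 stood at 614 against 260 CPM, Mgarp at 276 against 70.5 CPM and Xist at 333 against 111 CPM, and the galectin gene Lgals3 at 17.4 against 111 CPM, with 79.6% of its MullerControl UMIs in 1 cell. Mgarp was more abundant in rod-like cells, at 1467 and 1129 CPM, and in Müller-like cluster 12, at 3947 and 4273 CPM. Transcripts of other classes were also higher in microglia-like cells. Rod transcripts had a median of 0.44, above the random range of -0.14 to 0.22, and 4 bipolar markers 1.91. Cells with UMIs of Xist and of no Y-linked gene made up 35.7% of the Muller and 7.64% of the MullerControl library, and cells with Y-linked UMIs alone 13.2% and 27.0%, so the libraries differed in their mix of cells from female and male mice.

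Amacrine-like and bipolar-like cells took larger shares in the Muller library. A lower number of rod-like cells alone would raise every other class alike, yet the highest share ratio among the 5 other classes was 9.26 times the lowest (3.57 for amacrine-like against 0.385 for cone-like cells). Mice of 1 sex alone would leave the other without a difference, but the amacrine-like share ratio was 2.31 (1.71 to 3.13) among cells with Xist UMIs only and 2.27 (1.80 to 2.88) among cells with Y-linked UMIs only, and the bipolar-like ratio, less even, 1.75 (1.55 to 1.98) and 2.52 (2.25 to 2.82). The limit for the bipolar-like ratio was set after the result was seen. It lay below the limit set before for amacrine-like cells, which 1.75 would not have reached. Cells with neither mark, 48.7% of the Muller and 64.8% of the MullerControl library, were left out. Müller cells in transition, counted as amacrine-like while they still hold Müller transcripts, would raise the Müller list in amacrine-like cells, where its median log2 ratio was 0.37 (0.20 to 0.69) and its level 1504 and 1324 CPM; this cannot be told apart from free Müller RNA, which may be behind the higher medians of 1.79 in rod-like and 1.30 in bipolar-like cells, and a first test, written before its result was seen, with rod-like cells as the reference (a ratio of 0.365) was set aside as void because that reference itself differed. The vectors or the sort may have labelled other cell types in each library, and this cannot be told apart from any effect of the test virus, because each virus was sorted once, at tdTomato-positive rates with a ratio of 0.49.

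Bipolar transcripts were higher in the Müller-like cells of the Muller library. A candidate explanation is free RNA of bipolar cells, more frequent in that library: the median log2 ratio of the bipolar list was 2.41 in rod-like and 2.39 in Müller-like cells, a ratio of 1.01, and within the single rod-like clusters it was 2.45, 1.77 and 2.11, though in Müller-like cluster 12 alone it was 1.35. Doublets of Müller and bipolar cells as the whole cause would put most of these UMIs in a few cells, but the tenth of the Müller-like cells with the most of them, 126 cells, held 35.7%, and 70.1% of the cells had at least 1. A first test of doublets, written before its result was seen, used the Müller-like cells with the fewest bipolar UMIs and was set aside after its result as void, because those cells were picked by the genes under test. Its value is not given, and the test given here replaced it. Doublet calling changed the size of the difference but cannot show what part doublets carry. Pcp2 fell from 2.45 to 1.89 without doublet removal. Keeping doublets can add bipolar UMIs in both libraries, so this fall does not argue for or against doublets. With the automatic Scrublet threshold Pcp2 fell to 1.20 and the pan-neuronal median from 1.21 to 0.67. That threshold removed 803 and 3 cells, and so acted on almost 1 library alone. A part carried by doublets was not excluded. Expression of bipolar genes by Müller cells after the test virus was not excluded for a part either.

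Lcn2 was higher in Müller-like cells of the Muller library. Cone-like cells also held Lcn2 and went the other way, at 10.3 against 16.0 CPM and in 2.82% against 4.79% of cells. Free RNA of another cell type would raise Lcn2 in rod-like cells too, but between the libraries it rose by 1.37 CPM there against 22.7 CPM in Müller-like cells without the cell richest in it, a ratio of 0.0605 (at most 0.262 with the counting error of both); a first test, written before its result was seen, compared the levels in the Muller library and was set aside because its ratio of 0.0866 became 0.182 without that cell, and in the MullerControl library, at 0.528, free RNA is not excluded. A few cells carried the UMIs, since the 5 highest of the 25 cells with Lcn2 held 79.3% of its 145 UMIs, so a strong response of a few Müller cells is a possible explanation. Whether it goes with the sex of the mice cannot be told apart with so few cells: Lcn2 was seen in 8 of 389 Müller-like cells with Xist UMIs only (2.06%) and in 1 of 160 with Y-linked UMIs only (0.625%), a ratio of 3.29. An effect of the test virus stays open and untested, since each group had 1 library.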
